A study of Homo sapiens with 8 samples.

How the data were processed

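Chromatin accessibility was assayed by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in H9 human embryonic stem cells and in surface ectoderm derived from them. Per the labels' protocols, nuclei were isolated, transposed and amplified, and libraries were first sequenced shallowly and kept only if their enrichment at transcription start sites (TSSs) passed a set score. The submitters' processing notes name FastQC, Bowtie2, SAMtools, MACS2 and DESeq2, without versions, and the genome builds hg19 and GRCh37, which are 2 names for the same assembly. The thresholds, the role of each tool and any pooling of replicates are not given in the sources used here.

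The data analysed were 2 lists of sites made by the authors. The first holds sites that its name describes as opened by the morphogens, and the labels attach it to the wild-type samples at day 0 and day 7. The second holds sites that its name describes as opened by the morphogens and closed by p63, and the labels attach it to the wild-type and p63 knockout samples at day 7. Each list has 4 columns, which hold the chromosome, start, end and a numbered site name, and gives no count, signal, fold change or p-value for a site. Read depth is therefore unknown, no value per sample or replicate was analysed, and no test between cultures was made. All p-values below treat sites, or windows of the genome, as the units and describe these lists, not the spread between cultures. The direction of each change in accessibility is the authors' own and was not recomputed.

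Site names carry numbers that run along each chromosome in both lists, up to 1838350, so both lists appear to be drawn from 1 numbered catalogue of candidate regions. Between the first and last listed site of each chromosome the numbers span 1830280 entries, with a median of 1 entry per 1495 bp between neighbouring listed sites, and 0.775% of the entries are listed. Entries are not evenly spread: 10 Mb bins of chromosome X held up to 6036 of them, and the bin from 60 to 70 Mb held 3354. At 6 places the numbering jumps; the number of entries there was estimated from the distance in base pairs. Entries served as the denominator for the density of sites, which is given as sites per 1000 entries and takes account of assembly gaps. Positions are 1-based, on hg19.

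Overlap was counted with bedtools 2.31.1, with at least 1 bp shared, and compared with 1000 random placements of the second list that kept each site's width and chromosome and fell uniformly in base pairs between the first and last listed site. Distances between site centres were compared with the same kind of placement. Fixed windows of 1 Mb were tested for more sites than the catalogue entries predict with a one-sided Poisson test, and windows with at least 6 sites were tested for a different split between the lists with a two-sided Fisher's exact test. The number of windows called was compared with 100 circular shifts of the list labels along each chromosome. The share of the second list on each chromosome was tested by 10000 permutations of whole 1 Mb windows over chromosomes, since sites gather and are not independent. The list of neighbouring sites was compared with 1000 random assignments of list labels within chromosomes. Median widths were compared by a permutation test with 100000 resamples. Placement, label, chromosome and width tests were two-sided, and the test by label shifts was one-sided. Adjusted p-values use the Benjamini-Hochberg method within each family of windows or chromosomes, with a threshold of 0.05. Intervals are exact at 95% (Clopper-Pearson for shares, Poisson for densities) and cover counting error only. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

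The tests were tried on simulated data. With 200 windows given extra sites of the first list, the Poisson test found 0% of those with 2-fold as many sites (2935 windows tested), 66% of those with 4-fold (2936 tested) and 97% of those with 6-fold (2935 tested). In the same simulations the comparison of lists by window found 0% at 2-fold (1211 tested), 0% at 4-fold (1218 tested) and 18% at 6-fold (1266 tested, with 1 false call), so it misses most windows. Extra sites of the second list were not simulated. In 40 simulated sets with no difference between chromosomes, the chromosome test made 1 false call in all. In 1 further set, 30% of the second list's sites on chromosome 8 were given to the first list. Chromosome 8 was called there, with 1 false call elsewhere. List labels in these sets were drawn site by site, so neighbouring sites did not share a list as they do in the real lists. These counts therefore give no error rate for the real lists.

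Windows were named by a rule fixed before the data were examined, which applies when no gene annotation of the files' build is used. It takes the 10 windows of 1 Mb with the most sites in each list; ordering ties by the smaller Poisson p-value was added after the lists had been seen. The overlap test was also fixed then, with its alternatives by reciprocal overlap, identical ends and distance between centres; its placements by catalogue number and by whole catalogue entries were added later. The tests by window, chromosome, neighbour, distance and width were chosen after the lists had been seen. Planned comparisons with genes, TSSs, GC content, sequence motifs and fixed gene lists (surface ectoderm, keratinocyte, pluripotency, other germ layers and signalling pathways) were not run, because they need a genome and annotation of hg19, which were not used here. The gene table at hand is on GRCh38; only the chromosome of TP63 was taken from it. No site is therefore assigned to a gene.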

Results

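Accessible chromatin was profiled in 8 samples of the human embryonic stem cell line H9, in 4 groups of 2. Wild-type cells were taken before differentiation (day 0) and after 7 days in retinoic acid (1 uM) and BMP4 (5 ng/ml), the 2 morphogens used to turn pluripotent cells into surface ectoderm, the single-layered epithelium that precedes epidermis. Cells lacking p63 were taken at day 7 of the same treatment. A line carrying an inducible TP63 transgene was taken at day 0 after 2 days of doxycycline. TP63 encodes p63, a transcription factor of the p53 family required for stratified epithelia. The design asked how morphogens and p63 each change which sites are open. It was analysed here through the authors' 2 lists of sites. No list was analysed for the induced line, so p63 without morphogens is not described.

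The authors listed 8154 sites as opened by the morphogens, covering 14.0 Mb on 23 chromosomes. These "opened sites" had a median width of 1597 bp (quartiles 1222 and 2063 bp). They lay on every autosome and on chromosome X, at 4.46 sites per 1000 catalogue entries. The highest densities were on chromosome 21, with 5.70 (95% interval 4.70 to 6.84), chromosome 18, with 5.60 (4.96 to 6.29), and chromosome 8, with 5.57 (5.11 to 6.06). The lowest was on chromosome 15, with 3.16 (2.69 to 3.69). On chromosome X there were 401 opened sites, or 4.92% of the list (95% interval 4.46 to 5.41%).

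The opened sites were unevenly spread. The window of 1 Mb with the most opened sites was on chromosome 11, from 57000001 to 58000000. There 18 opened sites lay between 57056089 and 57828016 against 2.80 expected, a 6.43-fold excess. The window passed a Poisson test (adjusted p = 3.67e-06) but not a negative binomial test that allows for the general gathering of sites (adjusted p = 0.162). Adjoining windows on chromosome 8 also held many. There were 17 sites from 49000001 to 50000000, where 2.63 were expected, a slightly larger excess of 6.47-fold. From 48000001 to 49000000 there were 14 sites, where 2.85 were expected. Further windows on chromosome 8 held 15 opened sites, from 37000001 to 38000000, and 13, from 81000001 to 82000000. The other named windows were chromosome 16 from 86000001 to 87000000 with 14 sites, chromosome X from 131000001 to 132000000 with 13, chromosome 9 from 2000001 to 3000000 with 13, chromosome 5 from 167000001 to 168000000 with 13, and chromosome 7 from 155000001 to 156000000 with 12. All 10 passed the Poisson test, the weakest with an adjusted p of 0.00836, and none passed the negative binomial test (adjusted p from 0.162 to 0.793).

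In all, 59 of 2948 windows held more opened sites than their catalogue entries predicted, and these held 649 sites, 7.96% of the list. In 100 random sets placed by catalogue number, at most 2 windows were called. The counts per window varied with a variance 2.12 times their mean, against at most 1.26 in the random sets. With the negative binomial test 0 windows were called (smallest adjusted p = 0.135, in a window that is not among the named ones). At an unadjusted p under 0.05 there were 141 of 2948, no larger a share than the threshold itself. The dispersion of that test was fitted to the same windows, dense ones included, and its power was not simulated. The named windows are therefore given as the upper end of a broad spread. Of the opened sites, 40.3% had another opened site within 50 kb, against 24.6% in random placements (range 22.6 to 26.7%; permutation p = 0.002, the smallest that 1000 placements can give).

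The second comparison asked what p63 does to chromatin in cells that receive the morphogens. The authors listed 6037 sites as opened by the morphogens and closed by p63, covering 9.94 Mb, at 3.30 sites per 1000 catalogue entries. These "p63-closed sites" had a median width of 1531 bp (quartiles 1179 and 2005 bp). The 1 Mb window with the most of them was on chromosome 3, from 189000001 to 190000000. It held 16 p63-closed sites against 2.25 expected, a 7.11-fold excess, and 3 opened sites. It passed the Poisson test (adjusted p = 7.40e-06) but not the negative binomial test (adjusted p = 1, unadjusted p = 0.000706). The p63-closed sites there ran from 189003582 to 189835052, and the widest of them, 4096 bp, lay from 189507029 to 189511124. TP63, the gene deleted in the knockout, is on chromosome 3 in the gene table; its hg19 position was not used here, so whether this window holds it was not determined.

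**Figure D1:**
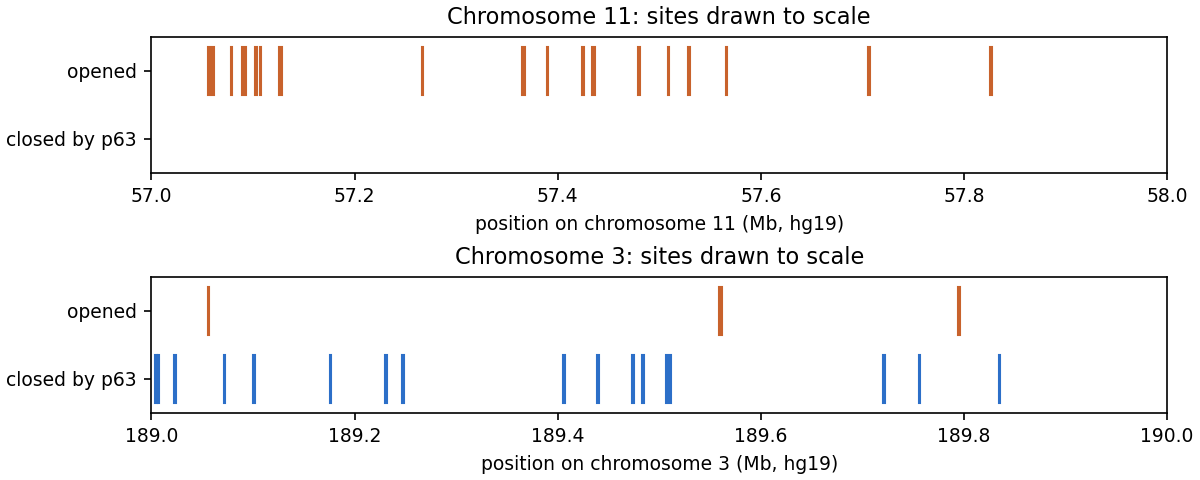
Sites in the 1 Mb window with the most sites of each list, drawn to scale along hg19 positions in Mb. Opened sites are in the upper row and p63-closed sites in the lower row of each panel. The chromosome 11 window holds 18 opened and 0 p63-closed sites; the chromosome 3 window holds 3 opened and 16 p63-closed sites.

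The other windows with the most p63-closed sites were chromosome 20 from 15000001 to 16000000 and chromosome 15 from 96000001 to 97000000, with 14 each, and chromosome 4 from 96000001 to 97000000, chromosome 9 from 89000001 to 90000000 and chromosome 2 from 67000001 to 68000000, with 13 each. Then came chromosome 2 from 123000001 to 124000000, chromosome 10 from 20000001 to 21000000, chromosome 3 from 25000001 to 26000000 and chromosome 12 from 115000001 to 116000000, with 12 each. All 10 passed the Poisson test, the weakest with an adjusted p of 0.00238, and none passed the negative binomial test (adjusted p = 1 for each). The p63-closed sites of the chromosome 3 window at 25 Mb lay within 383 kb. In total 70 of 2948 windows held more p63-closed sites than expected, and these held 710 sites, 11.8% of the list, where random sets gave at most 2 windows. The negative binomial test called 0 windows (119 of 2948 at an unadjusted p under 0.05, again no larger a share than the threshold). A Poisson expectation by base pairs called 107. Of the p63-closed sites, 41.8% had another within 50 kb, against 19.9% in random placements (range 18.0 to 22.3%; permutation p = 0.002, the smallest possible).

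The lists were then compared with each other, to ask whether the second list is part of the first. It was not. By its name the second list also holds sites opened by the morphogens, so this concerns the lists and not which sites opened. Of the 6037 p63-closed sites, 0 overlapped an opened site by 1 bp or more (exact 95% upper limit 0.0611%), and 0 site names were shared. Random placement gave a mean of 56.5 overlapping sites (range 36 to 80; permutation p = 0.002, the smallest possible), and drawing whole catalogue entries at random, which cannot overlap in part, gave a mean of 26.5 shared entries (range 12 to 50). How the lists were made is not stated in the sources used here; if they were made to exclude each other, the 0 was fixed in advance and this p carries no information. The closest pair from different lists was 47 bp apart. The lists are therefore separate sets of regions: a site is in the first or the second, and the 384 pairs of listed sites with consecutive catalogue numbers include 149 with both opened, 125 with both p63-closed and 110 with one of each. Which contrast of samples put a site in the second list rather than the first is not stated in the sources used here.

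Although they shared no site, the lists lay near each other more often than by chance. An opened site was found within 50 kb of 28.9% of p63-closed sites (1742 sites), against 21.8% in random placements (range 20.3 to 23.5%; permutation p = 0.002, the smallest possible). The median distance from a p63-closed site to the nearest opened site was 120 kb, against 156 kb in random placements by base pairs. Placement by catalogue number gave 146 kb, and so did shifting the p63-closed sites along each chromosome. Within 5 kb the shares were 3.45% and 2.72% (permutation p = 0.004).

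**Figure D2:**
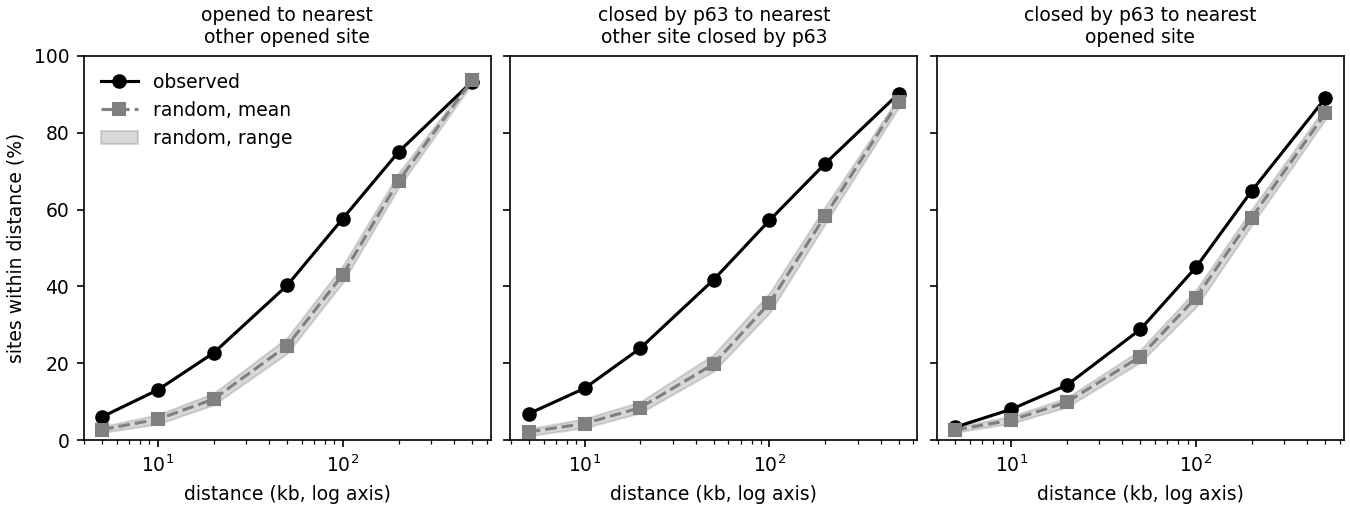
Share of sites (percent) with a neighbour within each distance (kb, log axis), for opened to opened, p63-closed to p63-closed and p63-closed to opened sites, with the mean and range of 1000 random placements. At 50 kb the observed shares are 40.3%, 41.8% and 28.9%, against 24.6%, 19.9% and 21.8% at random.

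Mixed neighbours were nonetheless rarer than random labels gave. Neighbouring listed sites came from the same list in 61.5% of pairs, against 52.3% when list labels were assigned at random within chromosomes (highest of 1000, 53.6%; permutation p = 0.002, the smallest possible). The excess was present for pairs up to 10 kb apart, at 66.8% against 51.9%, and for pairs 200 to 1000 kb apart, at 58.6% against 52.7% (adjusted permutation p = 0.0025 for both). For the 336 pairs more than 1000 kb apart it was near the threshold, at 60.7% against 55.3% (upper end of the central 95% of random labels 60.1%; adjusted permutation p = 0.0400). The longest autosomal stretch of opened sites with no p63-closed site between them held 38 sites, on chromosome 2 from 86789508 to 98343398, where random labels gave at most 36. On chromosome X the longest held 76, from 102023090 to 117966621, which was within the range of random labels there (mean 51.1, highest 117). The longest stretch of p63-closed sites held 21, on chromosome 2 from 139737162 to 142766294, where random labels gave at most 20.

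**Figure D3:**
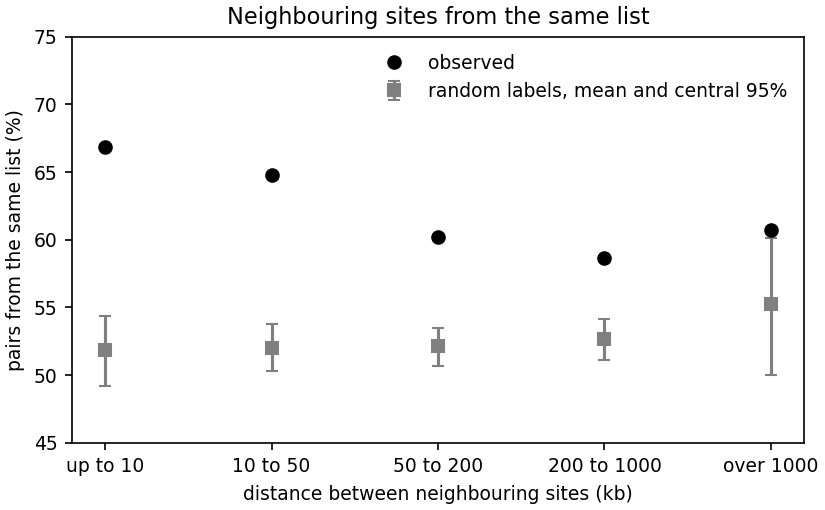
Share of neighbouring pairs of sites from the same list (percent) by the distance between them (kb); black points are observed and grey squares are the mean of 1000 random label assignments with their central 95%. The observed share is 66.8% up to 10 kb, 58.6% at 200 to 1000 kb and 60.7% beyond 1000 kb, where it lies just above the upper end of the random interval, 60.1%.

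Of 1072 windows with at least 6 sites, 10 were called as differing in their split between the lists (Fisher's exact test, adjusted). This test treats sites as independent, which neighbouring sites are not. When the list labels were shifted along each chromosome, so that stretches of each list stayed together, 100 shifts gave 0 to 13 calls (mean 2.57), and 8 of them gave at least 10 (one-sided permutation p = 0.0891). The count therefore did not pass the threshold against labels that gather in this way, and the windows are given as the most uneven ones. In 9 of them p63-closed sites were in excess, and 6 of these held no opened site. These 6 were 123000001 to 124000000, 126000001 to 127000000, 41000001 to 42000000 and 140000001 to 141000000 on chromosome 2, 80000001 to 81000000 on chromosome 11 and 107000001 to 108000000 on chromosome 10, each with 10 to 12 p63-closed sites. The first of them had an adjusted p of 0.0176 with 12 p63-closed sites. The windows at 15 Mb on chromosome 20 (14 p63-closed and 1 opened), 189 Mb on chromosome 3 (16 and 3) and 20 Mb on chromosome 10 (12 and 1) were also called. The window at 57 Mb on chromosome 11 was the only one called with an excess of opened sites (18 and 0; adjusted p = 0.0176). The 9-to-1 split partly follows from the sizes of the lists: a window without the other list needed 16 opened sites to reach the largest p called, but 10 p63-closed sites. Windows of 1 Mb shifted by 500 kb gave 3 calls, and windows of 500 kb, which hold fewer sites each, gave 1.

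The chromosomes also differed in their mix. Chromosome X had 32 p63-closed sites, 0.530% of that list (95% interval 0.363 to 0.747%), against 401 opened sites. Its density of p63-closed sites was 0.427 per 1000 entries, 0.125 times the autosomal density of 3.42 (95% interval of the ratio 0.0853 to 0.176), while its density of opened sites, 5.35, was 1.21 times the autosomal 4.42 (1.10 to 1.34). The p63-closed share of listed sites on chromosome X was 7.39% (5.11 to 10.3%; window permutation, adjusted p = 0.0023). The share was also low on chromosome 22, at 22.8% (15.7 to 31.2%; adjusted p = 0.0046), and chromosome 19, at 28.8% (22.8 to 35.4%; adjusted p = 0.0092), and high on chromosome 15, at 54.4% (49.0 to 59.7%; adjusted p = 0.0023). The other 19 chromosomes were not called. Permuting windows of 5 Mb left 2 calls, chromosomes 22 and X (adjusted p = 0.0391 and 0.0046). Without chromosome X, chromosome 8 was also called, at 36.1% (adjusted p = 0.0187).

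**Figure D4:**
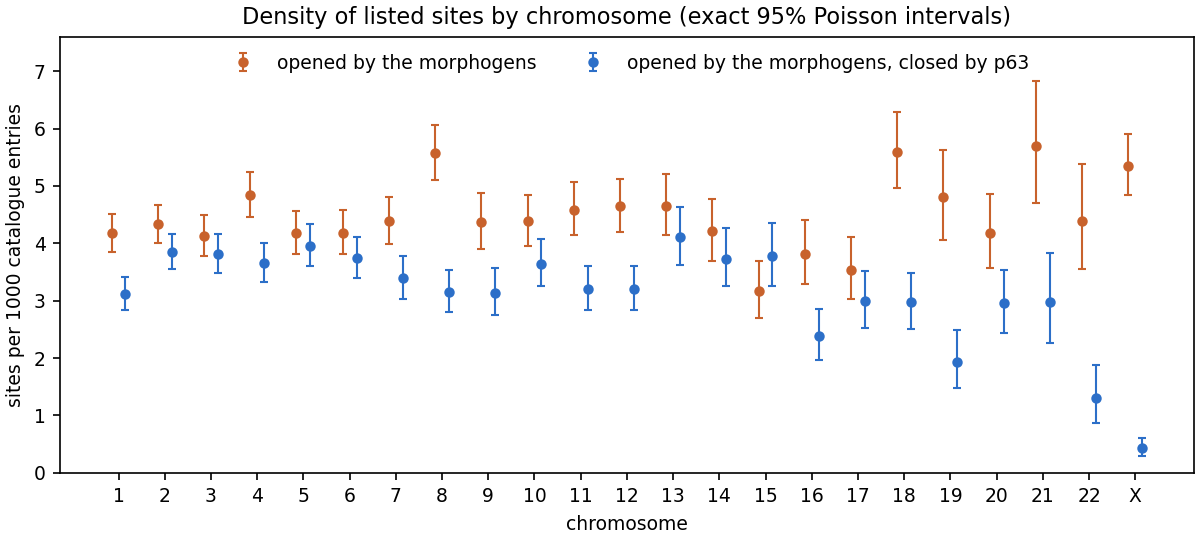
Sites per 1000 catalogue entries on each chromosome for opened and p63-closed sites, with exact 95% Poisson intervals for counting error. On chromosome X the p63-closed sites are at 0.427 and the opened sites at 5.35; on chromosome 15 the values are 3.77 and 3.16.

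**Figure D5:**
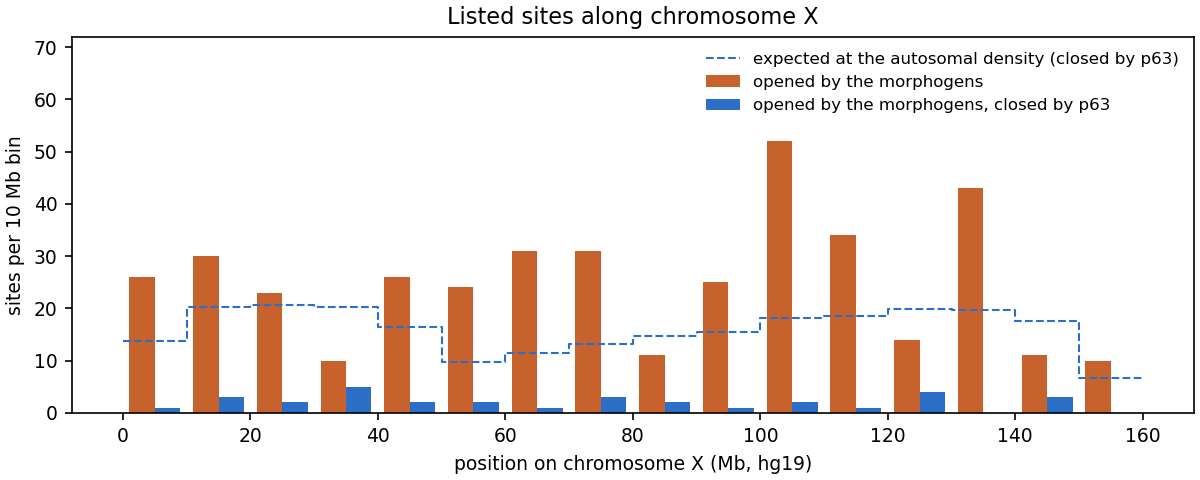
Number of opened and p63-closed sites in 10 Mb bins along chromosome X (hg19 positions in Mb), with the number of p63-closed sites expected at the autosomal density as a dashed line. In all 16 bins the p63-closed count, from 0 to 5, is below that line.

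Opened sites were slightly wider than p63-closed sites, by 66.0 bp in the median (bootstrap 95% interval 41.0 to 97.5 bp; permutation p = 1e-05, the smallest that 100000 resamples can give). This is a small part of the spread within either list.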

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

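No paired analysis was possible because the lists hold no values per sample; for the same reason no replicate could be left out in turn. The alternatives by merging of sites, reciprocal overlap, identical ends and distance between centres were fixed before the data were examined; the others were chosen after the lists had been seen. Of 33 alternative settings, 26 kept the result's direction and its side of the threshold or stayed within 1.5 times its count, and 7 moved a count. The 26 include settings that could not, or could hardly, come out otherwise. Among these are the stricter overlap settings and the neighbour comparisons without chromosome X or with sites within 10 kb joined. The tally is therefore no measure of how stable the results are. Merging touching sites left 8154 and 6037 sites. The overlap was also 0 sites with 50% reciprocal overlap, identical ends or centres within 500 bp. Reciprocal overlap and identical ends could give nothing else once 0 sites shared 1 bp. Centres within 500 bp hardly could, at median widths of 1597 and 1531 bp. These overlap settings therefore show no stability. The number of windows with more sites than expected went from 59 (opened) and 70 (p63-closed) to 0 and 0 with the negative binomial test, and for p63-closed sites to 107 with an expectation by base pairs, which left the opened sites at 61; the cause was not tested. Windows called as differing between lists went from 10 to 1 with 500 kb windows, which hold fewer sites each, and to 3 with shifted windows; the cause of the latter was not tested. Chromosomes that differed went from 4 to 10 with Fisher's exact test on sites, which treats gathered sites as independent, and to 2 with 5 Mb windows. A stricter threshold could not be tried, as the lists hold no score. The settings foreseen for TSS windows, GC content, motifs and genes were not run, for want of an hg19 genome and annotation. Depth is unknown, so sites missing from a list are not shown to be unchanged.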

Other observations

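The ends of the long arms differed in mix between the lists. In the last 5 Mb before the final listed site of each chromosome, taken as whole windows, there were 374 opened and 130 p63-closed sites. The density of opened sites there was 6.08 per 1000 catalogue entries, against 4.58 in the other windows that held a site, while that of p63-closed sites was 2.11 against 3.48. The p63-closed share was 25.8% at the ends and 43.2% elsewhere (permutation of windows, p = 0.0002, the smallest that 10000 can give), and it was lower at the end in 19 of 23 chromosomes. Without chromosome X the shares were 26.3% and 44.3%. This comparison was chosen after the lists had been seen. Its p treats windows as independent, but each end is a stretch of adjoining windows and neighbouring sites tended to share a list. The p may therefore be too small, and no permutation of whole stretches is given.

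In the weighing below, the tests on chromosome X and the placement by catalogue number were chosen after the values they use had been seen; the tests by joining sites, by leaving out chromosome X from the neighbour comparison and by shifting the list were set before theirs, except that joining the random labels too was added after a first run, because joining only the observed sites removes same-list pairs by construction.

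The p63-closed sites were few along the whole of chromosome X, with 0 to 5 in each 10 Mb bin, and 100% of these bins lay below the autosomal density. That share of bins is no separate test of a few empty stretches. With 32 sites in all, against 256 expected at the autosomal density, few bins could have reached it. A lack of power to list any site on chromosome X in the wild-type libraries would bear on both lists. It is argued against by the 401 opened sites there, 4.92% of their list, beside 32 p63-closed sites, 0.530% of theirs. The density of opened sites, 1.21 times the autosomal one, is per catalogue entry. If low power also left fewer entries on chromosome X, that ratio would hide it, and no ratio per base pair was made. A difference in the dosage or activity of chromosome X between the knockout and wild-type lines could give a ratio of 0.125 in a list that depends on both lines, but it cannot be told apart from an effect of p63 itself, because the lists hold no values per library. The p63 genotype is confounded with the line in this design and stays open, untested.

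Neighbouring sites came from the same list more often than random labels gave. Splitting of single open regions into several listed sites is argued against as the whole cause by pairs 200 to 1000 kb apart, at 58.6% against 52.7%. The widest listed site was 12362 bp. After sites of 1 list within 10 kb were joined, the excess over random labels joined in the same way was 9.10 percentage points, against 9.23 before. Joining adds no support, because 1472 of 14168 pairs lay within 10 kb, too few for the excess to fall far. Chromosome X, with 433 of 14191 sites, holds 3.05% of the pairs. That is less than the excess of 9.23 points over all pairs, so chromosome X alone cannot be the cause. Leaving it out, which gave an excess of 9.46 points, adds nothing to this, as it holds too few pairs for the test to come out otherwise. Large-scale properties that differ along chromosomes, such as GC content or gene density, were not tested.

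The p63-closed sites lay within 50 kb of an opened site in 28.9% of cases. The density of catalogue entries is argued against as the whole cause, since placement by catalogue number gave 22.7% (highest of 1000, 25.1%). The gathering of each list on its own is also argued against: shifting the p63-closed sites as a whole along each chromosome gave 22.7% (highest of 1000, 24.7%). That both lists follow regions with many regulatory elements stays open as a candidate explanation, since such regions could not be marked without an annotation.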
